A study of Mus musculus with 2 samples.

How the data were processed

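Gene expression was measured by droplet single-cell RNA sequencing of the 3′ ends of transcripts (10x Genomics chemistry, version 3 kit per the labels' protocols) in germinal center B cells sorted from the spleens of immunized mice. The series holds 2 libraries of 1 group, called library 1 and library 2 here after the numbers in their titles. The labels do not say whether the libraries came from separate animals, so p-values cover only these libraries. They rest on how far class differences disagree between the libraries, with dispersion shared across genes, and this disagreement may be technical. For each library the deposited matrix gives counts of unique molecular identifiers (UMIs, tags that mark single captured RNA molecules) per gene and cell barcode, not normalized, with 30905 genes listed. The matrices were written by Cell Ranger 3.0.2 per the file headers, against mm10 per the submitters' processing notes. Other settings of that step, such as the gene annotation and the rule for calling cells, were not given in the sources used here. Gene names and identifiers were taken from the deposited feature lists. Coordinates are those of GENCODE release M21 on mm10, matched by gene identifier and counted from 1, and transcript lengths came from the same annotation.

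The deposited counts came to 75121538 UMIs over 8765 barcodes in library 1 and 61874342 UMIs over 7868 barcodes in library 2. The choices that follow were fixed before the data were examined, except where a later choice is named as such. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet within scanpy 1.11.5 were removed. The genes and UMIs limits alone passed 8385 and 7672 barcodes, whereas all limits together passed 1488 and 1186, because the median mitochondrial share was 17.8% and 21.0%. Scrublet called 3 and 1 barcodes as doublets, 0.202% and 0.0843% of those passing, and 0 and 1 barcodes at a mitochondrial limit of 40%, but 10 and 25 (4.20% and 11.5%) at 5%. The rate thus differed between limits, most doublets may remain at the 10% limit, and an alternative without the highest 6% of doublet scores was added. Kept cells numbered 1485 and 1185, with median depths of 15908 and 15565 UMIs. Barcodes of 10% to 20% mitochondrial share had medians of 6952.5 and 6722 UMIs, so that the limit chose deeper cells, and limits of 20% and 40% were added as alternatives after seeing the data.

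Kept cells were clustered on log-normalized counts, using 2000 variable genes without immunoglobulin genes, 30 principal components, 15 neighbors and Leiden resolution 1.0 (igraph 0.11.9). Of the 14 clusters, 12 were called germinal center B-like from fixed marker genes. The rule that kept the other 2 clusters out was set after seeing the data. A cluster was left out if its median depth was below 1/3 of its library's (1 cluster, at 0.127) or if at least 5 markers of another class were raised at least 2-fold. The low-depth cluster held 94 cells of each library (6.33% and 7.93%), and the cluster with naive and memory B cell and macrophage markers held 45 and 40 cells (3.03% and 3.38%). The germinal center B-like class held 1346 and 1051 cells. Markers of 13 cell types had been fixed, namely germinal center, naive, marginal zone and memory B cells, plasmablasts, T cells, natural killer cells, macrophages, neutrophils, dendritic cells, erythroid cells, stromal cells and platelets.

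In all, 4 comparisons were made between classes of germinal center B-like cells inside the libraries. For gates and phases, each cell was thinned at random to 3900 UMIs, the 10th percentile rounded down, which left out 130 and 128 shallower kept cells. The zone gate used the genes of the flow cytometry gate for germinal center zones, read as RNA and not as protein. Light zone gate cells had at least 1 UMI of Cd83 or Cd86 and none of Cxcr4, and dark zone gate cells had at least 1 UMI of Cxcr4 and none of Cd83 or Cd86. Only 1 such UMI was found in 234 of 486 and 158 of 430 light zone gate cells, and in 130 of 157 and 106 of 137 dark zone gate cells. Both signals were found in 135 and 116 cells and neither in 502 and 324. A gene with no UMI may still be expressed, so the gates separate the zones only in part. IgG and IgM cells had at least 5 heavy chain constant region UMIs, at least 80% of them from Ighg genes or from Ighm and Ighd. Light zone gate cells with at least 1 Myc UMI were set against those with none. G2/M-like and G1-like cells were called from scores of fixed S phase and G2/M phase lists in scanpy. A phase is a range of a score, and 85 cells (6.64%) of library 1 and 52 cells (5.16%) of library 2 lay within 0.05 of a boundary. The phase was the same without thinning in 86.6% and 86.2% of cells. Keeping the called doublets, 4 more cells, redrew the thinning and the control genes of the score. G1-like cells then numbered 169 and 142 in place of 229 and 195. The S-like share was 35.5% and 36.2% in place of 24.5% and 25.0%. Genes that defined a class were left out of its test, as were immunoglobulin genes in the isotype comparison.

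Raw counts were summed per library and class, 4 sums per comparison, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3. The library was a block, since both sums of a library come from a single cell suspension, which leaves 1 residual degree of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM values (counts per 1000000) are given as mean ± SD over n = 2 libraries, and log2 fold changes with their standard error (SE). The 20 fixed gene lists were tested with camera and fry in limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. With an estimated correlation camera rests on the 1 residual degree of freedom, so hardly any list could pass. The lowest camera adjusted p was 0.375 there. In the zone comparison the G2/M phase list had an estimated correlation of 0.00571, below the preset value. Its camera adjusted p still rose from 1.73e-46 to 0.469. Failing in that setting therefore neither shows nor excludes that correlation between genes accounts for a result. Shares carry exact Clopper-Pearson 95% intervals and had no test, since 2 libraries cannot give an exact p of 0.05. Intervals and floors (3 counts) cover counting error only.

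The edgeR step was tested on simulated counts in which 200 genes were changed by 1.5-fold or 2-fold. It recovered 57% and 88% of them in the zone comparison (9752 genes), 75% and 93% in the isotype comparison (10365 genes), 21% and 56% in the Myc comparison (9408 genes), and 38% and 69% in the phase comparison (10226 genes). Calls among unchanged genes numbered 6, 8, 0 and 0. The real cells were also reassigned at random to classes of the same sizes, 20 times per comparison. Median calls were 7 genes for the zone, 10.5 for the isotype, 7.5 for the Myc and 13.5 for the phase comparison, and the highest were 65, 27, 103 and 40. The lowest were 0, 1, 0 and 1. Calls were thus common with no class difference, so the adjusted p-values of the blocked fit do not hold their nominal rate of false calls. Without the replicate block no draw called a gene, and the real classes had 687, 10, 99 and 2391 calls. For the zone effect by phase, zone labels were reassigned 99 times within library and phase, a test added after seeing the data.

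Genes were named by a fixed rule. Among genes past the threshold, with the same sign in both libraries and a mean of at least 20 CPM, it took the 12 largest increases and the 12 largest decreases per comparison. It added up to 4 members of each list with the largest change and 13 germinal center genes that were always eligible, and it left out gate, immunoglobulin, mitochondrial and unnamed genes. Between the libraries it took up to 5 genes over 2-fold apart in each direction. Not all eligible genes are printed. Copies with near-identical sequence (Bcl2a1b and Bcl2a1d, the Hist1h genes, the Iglc genes) can share reads, so their split is uncertain. Alternatives covered the test (DESeq2 1.42.0), RLE size factors, no filter on low counts, no replicate block, sums of thinned counts, the gates, the isotype purity, matching of phases, the mitochondrial limit, doublets, each library left out, the gene set test and the cluster resolution. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.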

Results

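Germinal center B cells, the antigen-activated B cells that mutate their antibody genes and are selected for binding, were profiled from mouse spleens. The mice were 8-week-old C57BL/6J, an inbred strain, immunized with sheep red blood cells, a particulate antigen that raises germinal centers. The 2 libraries held 75121538 and 61874342 UMIs. After filtering, 1346 germinal center B-like cells of library 1 and 1051 of library 2 were compared, at median depths of 16878 and 17184 UMIs. Nothing in the labels sets the libraries apart as conditions, so the comparisons are between cell states within them: the light and dark zones, switched and unswitched isotypes, Myc-detected and Myc-undetected light zone cells, and phases of the cell cycle.

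Marker genes described the sorted cells. All 11 germinal center B cell markers were detected in each of the 14 clusters, including those left out, and they entered the call of the class, so their detection did not set it apart. Cd79a, a signalling chain of the B cell receptor, had a UMI in 99.8% of germinal center B-like cells in each library, the class that the percentages here and in the next paragraph cover. Plasmablast genes split: Mzb1, a chaperone of antibody assembly, was found in 95.4% and 96.1% of cells, whereas Prdm1, the regulator that drives plasma cell fate, was found in 1.63% and 1.90%. Of 10 plasmablast markers, 6 passed 5% of cells. Of the naive B cell list, 6 of 8 markers passed 5%, with Fcmr, an IgM Fc receptor, highest at 83.5% and 87.9% of cells. Of 8 memory markers, 5 and 4 passed, with the ectonucleotidase gene Nt5e highest, at 20.7% in library 1. Of 5 marginal zone markers, 4 passed, with Dtx1 highest at 57.4% and 55.3%.

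Genes of other lineages were read in this class, from which a cluster with macrophage markers had been left out. The left-out cells of library 1 held C1qa at 105, C1qc at 78.3 and Lyz2 at 44.3 CPM, so the low values below describe the class and not the sorted sample. Among T cell genes the kinase Lck had a UMI in 51.0% and 52.5% of cells, but Cd3e, part of the T cell receptor complex, had none, which allows shares of up to 0.223% and 0.285% of cells with a UMI. The highest natural killer marker was Prf1 at 0.669% and 0.476%. The highest platelet marker was Itga2b at 0.297% and 0.381%. Of macrophage genes, only Cd68 passed 5% of cells (8.69% and 9.99%). Neutrophil genes reached at most 0% and 0.0951% of cells, and stromal genes 0.223% and 0.0951%. Flt3 (40.9% and 44.6%) and Bst2 (31.7% and 38.2%) from the dendritic list and Hbb-bt (35.7% and 34.7%) and Car2 (5.35% and 5.42%) from the erythroid list also passed 5%, without the other members of those lists. Hbb-bt stood at 42.4 and 37.9 CPM, whereas the globin genes Hbb-bs (1.09 and 1.44 CPM) and Hba-a1 (0.0725 and 0.279 CPM) and the erythroid heme synthesis gene Alas2 (0.0363 and 0 CPM) were far lower.

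The light zone, where germinal center B cells compete for antigen and T cell help, was set against the dark zone, where they divide and mutate. Light zone gate cells (486 and 430, median depths 15380.5 and 15152 UMIs) had higher Ccnd2, Il4i1, Batf, Nfkbia and Myc than dark zone gate cells (157 and 137, median depths 16365 and 18241 UMIs). Il4i1 (ENSMUSG00000074141, chromosome 7, 44816387 to 44840809), a secreted amino acid oxidase induced by interleukin 4, stood at 187 ± 38.5 CPM against 14.6 ± 0.0493 CPM (SD, n = 2), a log2 fold change of 3.66 ± 0.13 (SE; edgeR adjusted p = 3.97e-30). Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125162 to 127152193), a cyclin that carries cells into the cycle, had 1087 counts in the light zone gate and 4 in the dark zone gate. These counts are not scaled to depth: the light zone gate held 9450779 and 8318295 UMIs and the dark zone gate 2893341 and 2742391. Pafah1b3, a subunit of a lipid hydrolase, was lower in the light zone gate at 184 ± 10.6 against 375 ± 36.5 CPM (log2 fold change −1.03 ± 0.07, edgeR adjusted p = 2.14e-17).

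The light zone, NF-kB target, immediate early and switch factor lists were higher in the light zone gate by camera at its preset correlation. They did not pass with an estimated correlation or with fry (fry adjusted p = 0.202 for each). The estimated setting could hardly call any list, as it rests on 1 residual degree of freedom. All 18 measured light zone genes were called higher, 18 also when adjusted over the list alone (camera adjusted p = 1.90e-90, and adjusted p = 0.469 with an estimated correlation). Batf, a transcription factor of activated lymphocytes, rose by 3.18 ± 0.14 on the log2 scale, the survival genes Bcl2a1d and Bcl2a1b by 2.94 and 2.48, Irf4 by 2.68, the IgE receptor gene Fcer2a by 2.10 and the receptor gene Cd40 by 1.61. Of 14 measured NF-kB targets, which overlap the light zone list, 14 rose, 14 also when adjusted over the list alone (camera adjusted p = 5.18e-58, and adjusted p = 0.469 with an estimated correlation), among them the feedback inhibitor Nfkbia by 2.33 ± 0.10 and the NF-kB subunit Nfkb2 by 1.98. Of 11 immediate early genes of antigen receptor signalling, 8 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 4.52e-09, and adjusted p = 0.551 with an estimated correlation). Egr2 had 142 against 4 counts, not scaled to the larger UMI total of the light zone gate. Of 11 switch factors, 8 rose and 1 fell, 9 and 1 when adjusted over the list alone (camera adjusted p = 4.39e-14, and adjusted p = 0.469 with an estimated correlation). Tgfbr1, a receptor for TGF-beta, had a log2 fold change of −1.09.

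Growth and antigen presentation genes were also higher in the light zone gate. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), the growth regulator induced in selected cells, stood at 52.3 ± 19.5 against 11.0 ± 2.60 CPM (log2 fold change 2.22 ± 0.18, with 1.57 in library 1 and 2.81 in library 2, edgeR adjusted p = 4.99e-15). All 16 measured ribosome biogenesis genes rose, 16 also when adjusted over the list alone (camera adjusted p = 6.40e-27, and adjusted p = 0.469 with an estimated correlation), led by the spermidine synthase gene Srm (155 ± 45.2 against 58.0 ± 9.22 CPM). Of 10 MHC class II genes, 8 rose, 8 also when adjusted over the list alone (camera adjusted p = 5.18e-13, and adjusted p = 0.551 with an estimated correlation), with H2-Aa at 2002 ± 219 against 1251 ± 56.9 CPM and H2-DMb2 up by 0.66 on the log2 scale. Of 12 cholesterol synthesis genes, 9 rose, 9 also when adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.551 with an estimated correlation), including the sterol synthase gene Lss and the sterol sensor gene Insig1, at log2 fold changes of 0.93 and 0.60. Of 13 apoptosis genes, 5 rose and 2 fell, among them the survival gene Bcl2l1 with a log2 fold change of 1.31, but the list did not pass (camera adjusted p = 0.154).

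Dark zone and mitotic genes were lower in the light zone gate. Of 11 dark zone genes, 10 fell, 10 also when adjusted over the list alone, where 1 rose (camera adjusted p = 2.78e-15, and adjusted p = 0.551 with an estimated correlation). The adaptor gene Tifa had a log2 fold change of −1.81, the translesion polymerase gene Polh −1.34, the motility gene Gcsam −1.01 and the transcription factor gene Foxo1 −0.56. Of 50 G2/M phase genes, 47 fell, 48 when adjusted over the list alone (camera adjusted p = 1.73e-46, and adjusted p = 0.469 with an estimated correlation), with Cenpf at −0.93, Nek2 at −0.89 and the proliferation gene Mki67 at 868 ± 79.6 against 1414 ± 7.94 CPM. Of 42 S phase genes, 7 fell and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.808 with an estimated correlation). The largest decreases by the naming rule included the deubiquitinase gene Otub2 at −1.39, the selenium carrier gene Selenop at −1.35, the decoy chemokine receptor gene Ackr4 at −1.25, the end-joining ligase gene Lig4 at −1.15 and Rgcc at −1.15. Bcl6, the repressor that maintains the germinal center state, was lower by a smaller amount, −0.29 ± 0.09 (edgeR adjusted p = 0.0208), as were the confinement receptor gene S1pr2 at −0.28 and Bach2 at −0.57.

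In total 2223 of 9749 genes passed edgeR's test, 1180 higher and 1043 lower in the light zone gate, and 2219 of them had the same sign in both libraries. In cells drawn to equal phase shares, 1918 genes were called, 1642 of them shared, and 31 of 50 G2/M phase genes still fell (camera adjusted p = 5.03e-11, and adjusted p = 0.369 with an estimated correlation). The remaining lists did not pass camera: dissociation stress with 3 higher and 1 lower of 7 (adjusted p = 0.128), glycolysis 5 and 1 of 13 (0.0781) and oxidative phosphorylation 0 and 4 of 18 (0.119). Nor did DNA mutation and repair with 2 and 3 of 12 (0.181), migration and confinement 3 and 3 of 10 (0.813) or chromatin regulators 1 and 4 of 13 (0.117). The rest were interferon response 2 and 1 of 6 (0.379), plasma cell program 2 and 3 of 6 (0.747) and memory program 3 and 3 of 9 (0.747). Fry called only chromatin regulators in this comparison, as lower (fry adjusted p = 0.0344), and none of the lists that passed camera. Adjusted over the list alone, 6 glycolysis and 4 memory genes were higher, and 5 DNA mutation and repair and 4 migration genes lower. In the cells of equal phase shares, dissociation stress (4 higher and 1 lower of 7, 5 and 1 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.669 with an estimated correlation) and glycolysis (6 of 13 higher; camera adjusted p = 0.0206, and adjusted p = 0.767 with an estimated correlation) passed. At the 40% limit apoptosis genes passed (7 higher and 1 lower of 13; camera adjusted p = 0.0381, and adjusted p = 0.542 with an estimated correlation) and S phase genes did not (0.124). The count was 687 without the replicate block, 501 with DESeq2 and 718 on thinned sums. It was 908 with gates of 2 UMIs, 1363 with gates on unthinned counts, 313 in G1-like cells and 4308 when cells were split by list scores. At a mitochondrial limit of 5%, where the dark zone gate held 5 and 7 cells, edgeR called 0 genes, with 320 at an unadjusted p below 0.05.

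**Figure D1:**
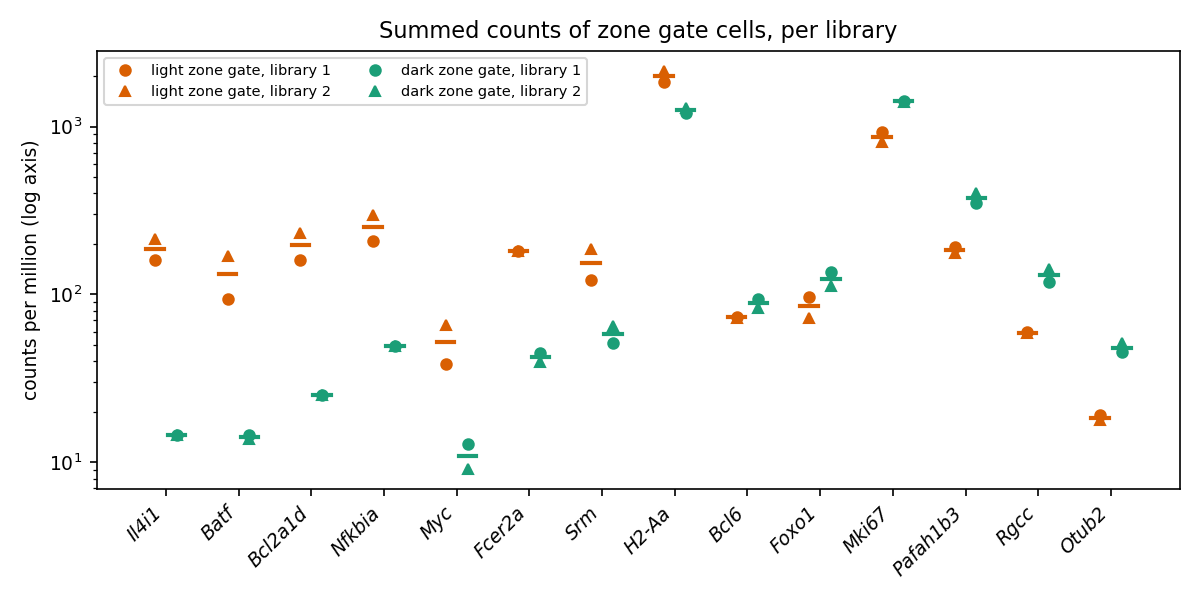
Summed expression of 14 genes in CPM on a log axis, for light zone gate and dark zone gate cells of each library, with symbols for libraries and bars for the mean of both. Il4i1 lies at 187 CPM on average in the light zone gate and 14.6 in the dark zone gate, and Pafah1b3 at 184 and 375.

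Cell cycle phase differed between the gates in both libraries. S-like or G2/M-like cells made up 346 of 486 light zone gate cells of library 1 (71.2%, exact 95% interval 66.9% to 75.2%) and 300 of 430 of library 2 (69.8%, 65.2% to 74.1%). In the dark zone gate they made up 142 of 157 cells (90.4%, 84.7% to 94.6%) and 127 of 137 cells (92.7%, 87.0% to 96.4%). The difference was 21.1 ± 2.60 percentage points (SD, n = 2), and without thinning the shares were 69.8% and 70.1% in the light zone gate against 93.0% and 92.3% in the dark zone gate. The difference was 13.7 points at a mitochondrial limit of 20%, 14.6 at 40% and 14.8 with the called doublets kept. In that last setting the light zone gate shares were 76.8% and 78.6%, above the intervals given here. The dark zone gate shares were 92.6% and 92.4%. The intervals thus leave out the spread of the phase call itself. Phase calls rest on transcript scores, not on DNA content.

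The difference in class-switched share between the gates was not stable across settings. Of germinal center B-like cells with enough heavy chain UMIs, 43.3% and 43.7% were IgM, 39.9% and 42.2% IgG (29.9% and 31.6% IgG1) and 16.7% and 14.1% mixed. IgA was found in 1 cell of library 1 and in none of 1030 in library 2, and IgE in none of 1313 and 1030 (exact upper limits 0.281% and 0.358%). Gates were read on thinned counts but isotypes on unthinned counts, so the isotype call was not held at a fixed depth. Among IgG and IgM cells, IgG cells made up 47.4% (42.4% to 52.4%) and 49.5% (44.2% to 54.7%) of the light zone gate. In the dark zone gate they made up 50% (41.0% to 59.0%) and 39.8% (30.7% to 49.5%). The difference was −3.51 ± 8.66 points (SD, n = 2), 2.62 in library 1 and −9.63 in library 2, so it was smaller than the spread between libraries. At limits of 20% and 40% it was 2.29 ± 0.87 points (2.90 and 1.68) and 4.36 ± 3.10 points (2.17 and 6.55), so that library 2 changed sign and library 1 did not, but the depth of thinning also differed there (3400 and 2600 UMIs). It was 0.49 points with unthinned gates (0.53 and 0.46) and 1.56 with the called doublets kept (6.37 and −3.25). At 40% the intervals of library 2 did not overlap (60.4% to 67.7% in the dark zone gate, 55.2% to 59.9% in the light zone gate). At a limit of 40% IgG cells made up 60% and 60.4% of IgG and IgM cells, against 48.2% and 48.7% at the 10% limit.

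**Figure D2:**
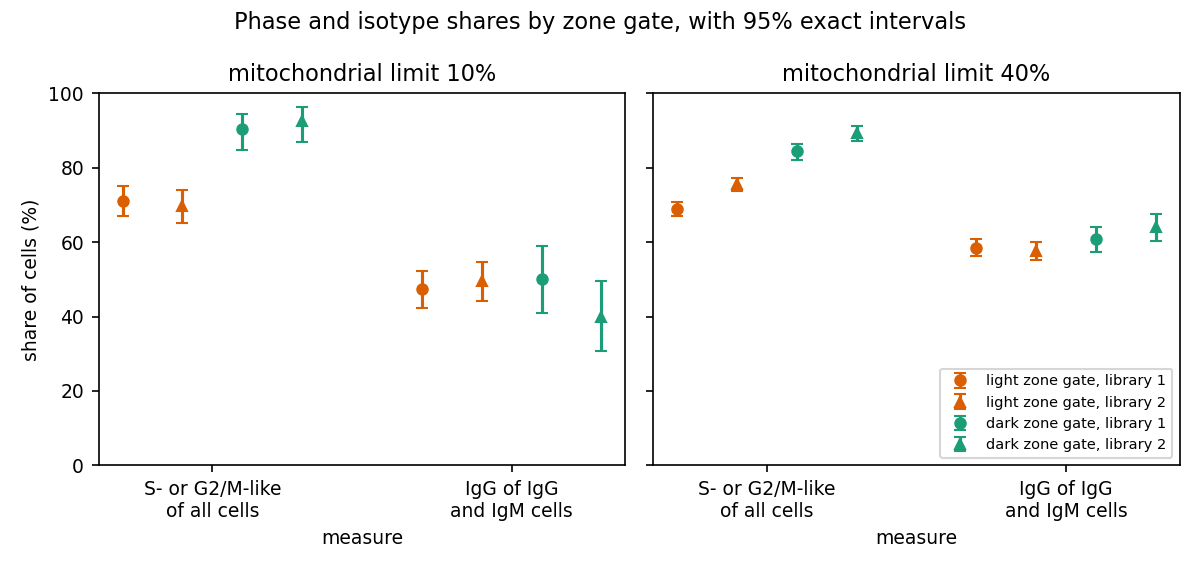
Percent of cells in S-like or G2/M-like phase and percent of IgG among IgG and IgM cells by zone gate, per library, with exact 95% intervals, at mitochondrial limits of 10% and 40%. The phase share is higher in the dark zone gate in each library at both limits (90.4% and 92.7% against 71.2% and 69.8% at 10%), while the IgG intervals of the gates overlap at the 10% limit and, in library 2, not at 40%.

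IgG cells were set against IgM cells to ask how class-switched germinal center cells differ from unswitched ones. The 524 and 435 IgG cells (median depths 18183.5 and 18265 UMIs) had more Slpi and less Cd72, Ly6d and Foxp1 than the 569 and 450 IgM cells (15726 and 15375 UMIs). Slpi (ENSMUSG00000017002, chromosome 2, 164354070 to 164389095), a secreted protease inhibitor, stood at 171 ± 12.6 against 71.1 ± 5.15 CPM (SD, n = 2), a log2 fold change of 1.24 ± 0.05 (edgeR adjusted p = 3.34e-22). Cd72 (ENSMUSG00000028459, chromosome 4, 43446462 to 43454628), an inhibitory coreceptor of the B cell receptor, stood at 62.7 ± 11.1 against 157 ± 19.4 CPM (log2 fold change −1.35 ± 0.05, edgeR adjusted p = 1.95e-22). Foxp1, a transcription factor of resting B cells, stood at 109 ± 9.18 against 215 ± 1.90 CPM.

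Beyond these, the transcription regulators Lmo2 and Batf rose in IgG cells by 0.75 and 0.64 on the log2 scale and Gcsam by 0.43. Ccnd2 rose by 0.86 ± 0.13, with 0.32 in library 1 and 1.54 in library 2. Ly6d had a log2 fold change of −1.24, Ms4a4c −1.09, the lipid carrier gene Apoe −0.80, Jun −0.78 and the interferon-induced gene Ifi27l2a −0.78. Of 12 cholesterol synthesis genes, 9 rose, 11 when adjusted over the list alone (camera adjusted p = 1.40e-12, and adjusted p = 0.563 with an estimated correlation). Lss rose by 0.54, Idi1 by 0.48, and Insig1 by 0.47, as did the sterol oxidase gene Msmo1, from outside the list, by 0.49. Of 10 MHC class II genes, 8 fell, 8 also when adjusted over the list alone (camera adjusted p = 1.70e-07, and adjusted p = 0.563 with an estimated correlation), by small amounts such as −0.27 for H2-Oa and −0.20 for the invariant chain gene Cd74. Of 9 memory program genes, 4 fell, 4 also when adjusted over the list alone (camera adjusted p = 0.00291, and adjusted p = 0.563 with an estimated correlation), among them the chemokine receptor gene Ccr6 at −1.34, Cd38 at −1.14 and Bcl2 at −0.82. Ly6d was also a leading gene of the left-out cluster with naive and memory B cell markers. The compared class was not cleared of memory-like cells, and whether these lay more among IgM cells was not tested.

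Of the genes always eligible for naming, Bcl6 had a log2 fold change of −0.01 (edgeR adjusted p = 0.943), Mki67 0.03 (0.681), Cxcr4 −0.03 (0.86) and Myc 0.26 (0.0747), none of them called. Cd83 at −0.29, Foxo1 at −0.20 and Bach2 at −0.19 were called lower. Bach2 turned to 0.0291 at the 40% mitochondrial limit and Cd83 to 0.0593 at the 5% limit, neither of them called there. Other lists also passed camera. Ribosome biogenesis had 8 of 16 higher, 12 when adjusted over the list alone (camera adjusted p = 2.22e-06), and glycolysis 6 of 13 higher (0.000741). Dissociation stress had 4 of 8 higher (0.00178). NF-kB targets had 7 higher and 2 lower of 15, 9 and 2 when adjusted over the list alone (0.0156). Both classes of a library came from the same cell suspension, so the dissociation stress list does not show that they were handled differently. Lower lists were dark zone genes with 1 higher and 4 lower of 11 (0.00446), immediate early genes with 4 of 11 lower (0.018) and migration genes with 4 of 10 lower (1 higher and 5 lower adjusted over the list alone; 0.0233). Each had adjusted p = 0.563 with an estimated correlation, except immediate early genes at adjusted p = 0.636 with an estimated correlation. In total 907 of 10347 genes were called, 407 higher and 500 lower, and 907 of them had the same sign in both libraries. The count was 10 without the replicate block, 110 with DESeq2, 132 on thinned sums and 579 with IgG1 cells. The majority of lower genes turned with RLE size factors (520 higher, 515 lower) and at an isotype purity of 95% (657 and 622). It was 25, 1377 and 3003 at mitochondrial limits of 5%, 20% and 40%. At 40%, cholesterol synthesis (12 of 12 higher, camera adjusted p = 2.69e-10, and adjusted p = 0.778 with an estimated correlation), MHC class II genes (7 lower and 2 higher of 10, 3.15e-05) and dark zone genes (6 lower and 4 higher of 11, 0.00653) still passed. Oxidative phosphorylation (8 of 18 lower, 0.000519) and the plasma cell program (4 of 8 lower, 0.00219) newly passed, and each of these had adjusted p = 0.778 with an estimated correlation. Ribosome biogenesis did not (2 higher and 2 lower, camera adjusted p = 0.986), nor did memory, dissociation stress, glycolysis, NF-kB, immediate early and migration genes.

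Myc marks light zone cells that have received selecting signals, so light zone gate cells with a Myc UMI were set against those with none. The 32 and 57 Myc-detected cells (median depths 18330 and 18336 UMIs) had higher Tnfaip3, Ccnd2, Batf and Nfkbia and lower Brwd1 and Bcl6 than the 454 and 373 Myc-undetected cells (15317.5 and 14630 UMIs). Nfkbia stood at 639 ± 112 against 202 ± 30.3 CPM (SD, n = 2), a log2 fold change of 1.64 ± 0.08 (edgeR adjusted p = 4.30e-80). Brwd1, a chromatin reader, stood at 37.1 ± 1.84 against 106 ± 4.73 CPM (log2 fold change −1.51 ± 0.17, edgeR adjusted p = 3.01e-17) and Bcl6 at 40.1 ± 2.08 against 77.4 ± 1.19 CPM (−0.95 ± 0.17, edgeR adjusted p = 1.27e-06).

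Signalling and growth lists were higher in Myc-detected cells. Of 18 light zone genes, 16 rose, 16 also when adjusted over the list alone, where 1 fell (camera adjusted p = 1.02e-29, and adjusted p = 0.423 with an estimated correlation). Of 15 NF-kB targets, 14 rose, 15 when adjusted over the list alone (camera adjusted p = 5.86e-29, and adjusted p = 0.423 with an estimated correlation). The log2 fold change was 2.26 ± 0.21 for the NF-kB feedback gene Tnfaip3, 2.02 for Ccnd2, 1.85 for Batf, 1.71 for the demethylase gene Kdm6b, 1.51 for Bcl2l1 and 1.42 for Irf4. The stress gene Gadd45g rose by 2.06 ± 0.24, with 0.84 in library 1 and 2.88 in library 2. Of 16 ribosome biogenesis genes, 15 rose, 16 when adjusted over the list alone (camera adjusted p = 3.68e-21, and adjusted p = 0.518 with an estimated correlation), with Srm at 0.93, the RNA polymerase I gene Polr1b at 0.90 and Gnl3 at 0.87. Polr1b turned to −0.54 on thinned sums, where it was not called. Of 11 immediate early genes, 8 rose and 1 fell, 8 and 2 when adjusted over the list alone (camera adjusted p = 1.40e-09, and adjusted p = 0.425 with an estimated correlation), with Nr4a1 at 2.42 and Egr3 at 1.84. Of 13 glycolysis genes, 6 rose, 7 when adjusted over the list alone, where 1 fell (camera adjusted p = 0.000593, and adjusted p = 0.532 with an estimated correlation), with the hexokinase gene Hk2 at 1.18 and the glucose transporter gene Slc2a1 at 1.03. Of 11 switch factors 5 rose, 6 when adjusted over the list alone (camera adjusted p = 7.83e-06, and adjusted p = 0.425 with an estimated correlation). Of 7 dissociation stress genes 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.532 with an estimated correlation).

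Dark zone and mitotic genes were lower in Myc-detected cells. Of 11 dark zone genes, 7 fell, 8 when adjusted over the list alone (camera adjusted p = 5.53e-09, and adjusted p = 0.425 with an estimated correlation), with Pafah1b3 at −1.13 on the log2 scale. Of 50 G2/M phase genes, 23 fell, 33 when adjusted over the list alone (camera adjusted p = 1.39e-15, and adjusted p = 0.423 with an estimated correlation), with the cytokinesis gene Anln at −1.83 and Mki67 at −0.41. In phase-matched cells 8 of 48 G2/M phase genes fell, 11 when adjusted over the list alone (camera adjusted p = 0.000126, and adjusted p = 0.570 with an estimated correlation). Of 42 S phase genes, 6 fell, 6 also when adjusted over the list alone (camera adjusted p = 0.000506, and adjusted p = 0.425 with an estimated correlation). At the 40% limit that list turned direction, with 5 higher and none lower, 3 higher when adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.487 with an estimated correlation). Cholesterol synthesis and memory genes, which did not pass here (camera adjusted p = 0.693 and 0.0536), passed at that limit (0.0234 and 0.00814), with adjusted p = 0.691 and adjusted p = 0.487 with an estimated correlation. Other decreases were the filament gene Vim at −1.42, Rgcc at −1.25 (−0.66 and −1.70 by library), the DNA repair gene Hmces at −1.21 (−0.68 and −1.75), S1pr2 at −0.77 and Bach2 at −0.66. In total 1088 of 9404 genes were called, 594 higher and 494 lower, and 1076 of them had the same sign in both libraries. The count was 69 without the cluster highest in Myc, 99 without the replicate block (78.8% of calls higher, against 54.6%), 143 with DESeq2 and 201 on thinned sums. With no filter on low counts it was 936, and the majority turned, with 428 higher and 508 lower. It was 718 in phase-matched cells, 659 over all germinal center B-like cells and 3841 with Myc read from unthinned counts. It was 1791 at a mitochondrial limit of 20% and 1 at 5%, where 1 and 2 Myc-detected cells remained. A cell with no Myc UMI may still express Myc, since detection rests on few molecules per cell.

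**Figure D3:**
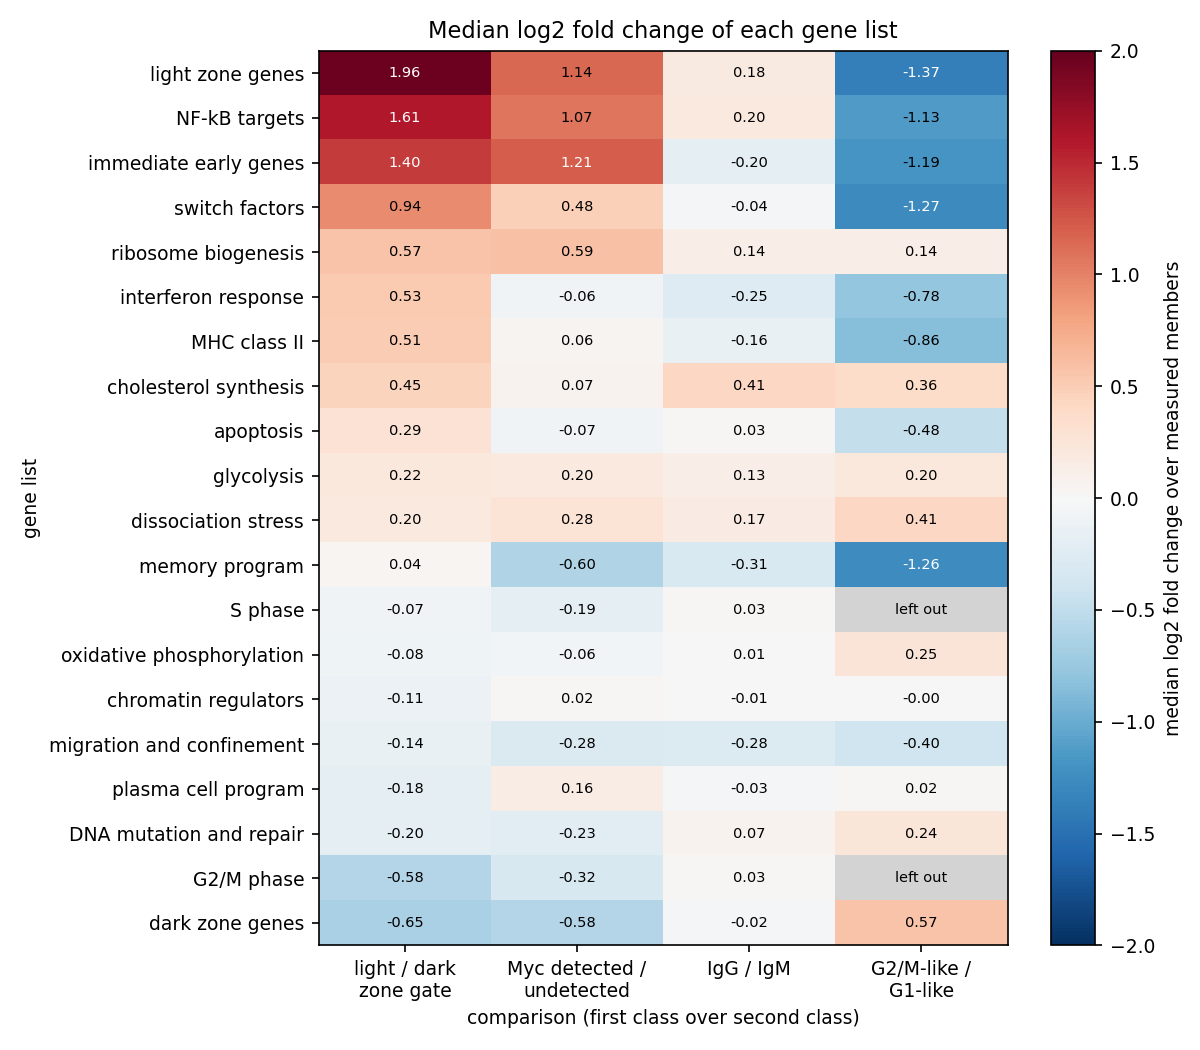
Median log2 fold change of each fixed gene list over its measured members (color and printed value) in the 4 comparisons, first class over second class. Light zone genes have medians of 1.96 between zone gates, 1.14 between Myc classes, 0.18 between isotypes and −1.37 between phases, and the phase lists are left out where they defined the classes.

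G2/M-like cells were set against G1-like cells to ask which programs go with the cell cycle. The 737 and 560 G2/M-like cells (median depths 21323 and 21376.5 UMIs) had more mitotic transcripts and less Cd83, Cd86 and Il4i1 than the 229 and 195 G1-like cells (9942 and 10041 UMIs). Plk1 (ENSMUSG00000030867, chromosome 7, 122159439 to 122169873), a mitotic kinase that was not in the phase lists, stood at 173 ± 3.38 against 2.13 ± 0.861 CPM (SD, n = 2), a log2 fold change of 6.40 ± 0.18 (edgeR adjusted p = 3.18e-260). Cd86, the costimulatory ligand of the light zone gate, stood at 53.9 ± 6.17 against 157 ± 22.3 CPM (log2 fold change −1.52 ± 0.08, edgeR adjusted p = 1.30e-86). Bcl6 (log2 fold change −0.04, edgeR adjusted p = 0.724) was not called. The phase classes were not matched for zone. Of the 229 and 195 G1-like cells, 140 and 130 lay in the light zone gate and 15 and 10 in the dark zone gate. Of the 737 and 560 G2/M-like cells, 214 and 185 lay in the light zone gate and 112 and 92 in the dark zone gate. A cluster with memory markers raised, 90.3% G1-like, was kept too. Zone and memory-like cells may thus contribute to the lower light zone and memory genes.

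Other mitotic genes were higher in the G2/M-like cells, a result that the phase call itself favors, with log2 fold changes of 6.53 for Sgol2a (5.89 and 6.81 by library), 5.99 for Kifc1 (6.56 and 5.08), 5.25 for Kif20a (5.91 and 4.53) and 4.67 for Ccna2. Light zone genes fell with them: 18 of 18, 18 also when adjusted over the list alone (camera adjusted p = 1.66e-38, and adjusted p = 0.375 with an estimated correlation), with Il4i1 at −2.84, Fcer2a at −1.81 and Bcl2a1b at −1.78. All 10 MHC class II genes fell, 10 also when adjusted over the list alone (camera adjusted p = 6.58e-24, and adjusted p = 0.375 with an estimated correlation), with H2-Oa at −1.21, the class II transactivator gene Ciita at −1.08 and Cd74 at −0.92. Of 15 NF-kB targets 14 fell (camera adjusted p = 2.28e-19), and of 11 switch factors 9 fell (4.49e-10). Of 11 immediate early genes 9 fell (7.27e-10), including Egr3 at −4.19. Each of these lists had the same count when adjusted over the list alone, and adjusted p = 0.375 with an estimated correlation. Cxcr4 rose by 0.40, and Slfn2, Ccnd2, Cd83 and Myc had log2 fold changes of −2.28, −2.13, −2.01 and −1.05.

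Metabolic and stress lists also passed camera. Of 18 oxidative phosphorylation genes, 14 rose and 1 fell (camera adjusted p = 0.00561), with Sdhd at 0.50 and Sdhb at 0.42. Of 13 glycolysis genes 7 rose and 1 fell (0.0199). Of 7 dissociation stress genes, which encode chaperones, 6 rose (3.98e-05), with Hsph1 at 1.16 and Hsp90aa1 at 1.08. Of 13 apoptosis genes 9 fell and 2 rose (0.0185), with the survival gene Bcl2l1 at −1.72 and the death gene Bmf at −1.66. Of 10 migration genes 6 fell (0.00364), with Cxcr5 at −1.12. Of 9 memory genes 5 fell and 1 rose (0.0093), and of 7 interferon genes 6 fell (0.0468). Of 13 chromatin regulators 5 rose and 2 fell (0.0468), with the histone methyltransferase genes Ezh2 and Suz12 at 1.59 and 0.97 and the DNA methyltransferase gene Dnmt1 at 0.97. Adjusted p = 0.375 with an estimated correlation applied to each of these lists, except adjusted p = 0.376 with an estimated correlation for interferon genes and chromatin regulators. Adjusted over the list alone, 10 apoptosis genes fell and 6 chromatin regulators rose, and the other counts were the same. Dark zone genes, with 7 higher and 3 lower of 11 (camera adjusted p = 0.195), did not pass, although Polh rose by 3.19 and Foxp1 had a log2 fold change of −1.26. Cholesterol synthesis (8 higher of 12, 0.0885), ribosome biogenesis (6 higher and 3 lower of 16, 0.134), DNA mutation and repair (3 higher and 1 lower of 8, 0.0885) and the plasma cell program (2 higher and 1 lower of 7, 0.692) did not pass either. At the 40% limit chromatin regulators (5 higher and 6 lower of 13, camera adjusted p = 0.103) and interferon genes (0.103) no longer passed, whereas cholesterol synthesis (12 of 12 higher, 0.00266), ribosome biogenesis (9 higher and 1 lower of 16, 0.0285) and DNA mutation and repair (5 of 8 higher, 0.0285) did, each at adjusted p = 0.55 with an estimated correlation.

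In total 4243 of 10134 genes were called between the phases, 2147 higher and 2096 lower, and 4232 of them had the same sign in both libraries. The count was 2391 without the replicate block, 1695 with DESeq2 (60.7% of calls higher, against 50.6%), 2309 on thinned sums and 351 at a mitochondrial limit of 5%. At 40% the majority turned, with 3057 higher and 3136 lower. In the dark zone gate alone, with 15 and 10 G1-like cells, it was 369.

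Both libraries gave similar profiles. Over 5372 genes of at least 20 CPM, the correlation across genes was 0.991 (Pearson) and 0.986 (Spearman), where genes are not independent replicates. Of these genes 13 were over 2-fold apart, and each was higher in library 1. The farthest were the replication-dependent histone genes Hist1h2ap at 327 against 88.1 CPM and Hist1h2ae at 153 against 63.6 CPM and the unnamed gene Gm10076 at 186 against 68.4 CPM. Next were the RNA polymerase subunit gene Polr2l at 57.3 against 24.2 CPM and the ribosomal protein gene Rpl35 at 1718 against 769 CPM. The labels list the libraries as 2 samples, and they were used as such.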

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

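The tests of lambda light chain UMIs, of the S-like share, of short genes outside the pattern and of the zone effect by phase were chosen after the result was seen, whereas the test of transcript length was chosen before.

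Between phases, the zone effect differed for 69 of 8779 genes by edgeR's interaction test, a difference between groups under a single contrast, with 25 called on thinned sums (22 shared) and 157 at the 40% limit (34 shared). The log2 effect of light over dark zone gate was higher in G1-like than in G2/M-like cells for 59 of them and lower, as for Tgfbr1 at −2.33 against −0.90, for 10, and 22 encode ribosomal proteins. The G1-like dark zone gate held only 15 and 10 cells, so chance in few cells was weighed by reassigning the zone labels at random 99 times within library and phase: 3 of the 100 counts, the real one included, reached 69, with a median of 5. That is below a share of 0.05, but the reassignment removed the zone effect itself in both phases. It therefore cannot exclude chance for a zone effect that differs between phases, and 2 reassignments called more genes, 81 and 88. In other cells of these libraries, those over 10% and up to 40% mitochondrial UMIs, 88.4% of the 69 genes had a difference of the same sign, but these genes can move together, the median difference was 0.16 there against 0.70 and only 11 were called again, and no biological explanation was tested.

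Lambda light chain UMIs appeared in cells whose light chain is kappa, a signal outside the compared measurements and above what a count of 0 allows. Kappa-dominant cells (1240 and 969, at most 50% lambda among at least 20 light chain UMIs) held 9.78 and 9.03 lambda UMIs per 10000, with medians of 16 and 14 lambda UMIs per cell. Free RNA would reach every droplet with 5.52 and 5.54 kappa UMIs per lambda UMI, the ratio over all cells, and so bring 132 and 113 kappa UMIs beside the median lambda UMIs of cells of at least the median depth, yet 10 and 11 of these cells had under 10% of that, with medians of 1 and 3 kappa UMIs. Doublets would touch a minority of cells, but at least 99.4% of kappa-dominant cells had a lambda UMI. Doublets are excluded as the main source, and so is free RNA if it holds the kappa to lambda ratio of the cells. That ratio was assumed for free RNA and not measured in empty droplets. Transcription of lambda constant regions in kappa cells and reads shared between gene copies stay open and untested, and no biological explanation was tested.

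The genes over 2-fold apart between the libraries were weighed as well. Loss of the shortest transcripts in library 2 may account for 8 of the 13, those of at most 600 nucleotides: such genes had a median log2 ratio of library 2 over library 1 lower by −0.70 than genes over 4000, and it was −0.58 in the 40 of them that were neither histone genes nor over 2-fold apart. The fall stopped there, with medians of 0.0788 at 600 to 1000 and 0.178 at 1000 to 2000 nucleotides against 0.0029 over 4000 (Spearman correlation with length −0.344), so the other 5 genes stay open. A smaller share of S phase cells in library 2 cannot be told apart for the histone genes: the S-like share was 0.494 percentage points higher there, but a cluster led by Hist1h genes was 83.0% G2/M-like, so the call does not follow these genes, and it held 12.3% of library 1 and 8.10% of library 2, while another such cluster (94.7% G2/M-like) held 8.22% and 10.5%. Whether the loss arose at library preparation or in read processing was not tested, and no biological explanation was tested.

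Cells left out of the comparisons also carried signals above what a count of 0 allows. C1qa, a macrophage complement gene, stood at 105 CPM outside the germinal center B-like cells of library 1, from 4 of 139 cells, with 1 of 134 cells in library 2. Klf2, a factor of resting B cells, stood at 10.9 counts per 10000 in the cluster with naive and memory B cell markers.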

How the results depend on the processing

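The limits of 20% and 40% mitochondrial UMIs, the removal of the highest doublet scores and the omission of the cluster highest in Myc were chosen after seeing the data, and the other alternatives before the data were examined. Genes called between zone gates (2223) moved to 687 with no replicate block, 501 with DESeq2, 718 on thinned sums, 908 with gates of 2 UMIs, 1363 with unthinned gates, 313 in G1-like cells, 4308 with a split by list scores and 0 at the 5% limit (edgeR, 320 at unadjusted p below 0.05). Between isotypes (907) they moved to 10 with no replicate block, 110 with DESeq2, 132 on thinned sums, 579 with IgG1 cells, and 25, 1377 and 3003 at limits of 5%, 20% and 40%. Between Myc classes (1088) they moved to 99 with no replicate block, 143 with DESeq2, 201 on thinned sums, 3841 with unthinned Myc counts, 718 in phase-matched cells, 659 over all germinal center B-like cells, 69 without the cluster highest in Myc, and 1 and 1791 at limits of 5% and 20%. Between phases (4243) they moved to 2391 with no replicate block, 1695 with DESeq2, 2309 on thinned sums, 369 in the dark zone gate and 351 at the 5% limit. The cycling share difference of 21.1 points was 13.7 and 14.6 at limits of 20% and 40% and 14.8 with called doublets kept, where 4 more cells redrew the thinning and the control genes of the phase score. It ranged from 19.3 to 22.9 when a library was left out. The IgG share difference of −3.51 points was 6.62 with gates of 2 UMIs and −18.6 at the 5% limit. It also turned direction by less than the spread between libraries, to 2.29 and 4.36 at limits of 20% and 40%, where both libraries had this sign, 0.49 with unthinned gates and 1.56 with called doublets kept. It ranged from −9.63 to 2.62 when a library was left out. Clusters numbered 8 in place of 14 both at resolution 0.5 and at the 5% limit. Of 20 lists camera called 10 for the zone, isotype and Myc comparisons, and of 18 lists 13 for the phase comparison, and fry called 1, 1, 0 and 1. With an estimated correlation camera called 0 in each, where 1 residual degree of freedom lets hardly any list pass. With a library left out there was no residual degree of freedom, so folds were given with no test and no count. Of single genes, 22 results turned direction where the main or the alternative fit called the gene. At the 5% limit these were Bach2 at 0.29 and Cenpf at 0.18 on the log2 scale between zone gates, Cd83 at 0.0593 between isotypes, H2-Oa at 0.38 and Foxp1 at 0.0476 between phases, and between Myc classes Ccnd2 at −1.34, Batf at −1.29, Brwd1 at 1.07, Vim at 0.0439, Pafah1b3 at 0.40, Bach2 at 0.70, Srm at −1.42, Polr1b at −0.43, Gnl3 at −0.39 and Mki67 at 0.16. Polr1b was also −0.54 on thinned sums. At the 40% limit Srm was −0.0063, Npm1 −0.0701 and Bach2 0.0291 between isotypes, and in the dark zone gate Cd83 was 0.31, Cxcr4 −0.96 and Myc 0.0754 between phases. Cd83 and Cxcr4 define that gate, so their turn there is set by the gate. Fewer cells limit the 5% setting and fewer counts the thinned sums. For the other settings the cause was not tested. Of the other single-gene results, 1838 were counted as the same. Among those with a test, the side of the threshold was kept, and direction too unless neither fit called the gene. Those with library 1 or library 2 left out, 131 and 130, had no test and stayed within the spread between libraries. The fold of both libraries mostly lies near the middle of the 2 single folds. Nearly every gene meets this rule for that reason, so these results are no sign of stability. A further 252 kept direction but no longer passed, and 14 kept direction and newly passed. The last 11, each with a library left out, moved by more than that spread.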

Other observations

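The effect of the zone gate by isotype and the cluster features below were examined after the data were seen, except that the cluster method was fixed before.

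A small cluster combined high Myc with low Bcl6. It held 24 cells of library 1 and 36 of library 2 (1.62% and 3.04% of kept cells), with a mean of 2.19 Myc, 8.03 Batf and 4.54 Ccnd2 counts per 10000, and only 0.115 Bcl6. In a cluster led by the mitotic genes Cenpf, Aspm and Nek2 the levels were 1.09 Bcl6 and 0.0333 Myc counts per 10000. A deep cluster of 138 and 116 cells, with a median of 43966.5 UMIs, was led by Srm (2.68 counts per 10000), Hspd1 and C1qbp, genes of polyamine synthesis and mitochondrial protein handling. A shallow one of 100 and 72 cells was led by Trim7 and Fcer2a, also had Ciita among its 10 leading genes, and was 90.3% G1-like. It also had 4 memory, 2 naive and 2 marginal zone B cell markers raised, fewer than the 5 of a single class that left a cluster out, with 0.564 Cd38 and 0.425 Ccr6 counts per 10000 against 0.0550 and 0 in the mitotic cluster. The compared class was thus not cleared of memory-like cells. The light zone gate held 78 Ccr6 and 117 Bcl2 counts against 0 and 5 in the dark zone gate, not scaled to its smaller UMI total. These genes define the clusters, so they are descriptions and not tests.

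No gene was called for a zone effect that differed between IgG and IgM cells. EdgeR's interaction test called 0 of 9102 genes, with 418 at an unadjusted p below 0.05 and a lowest adjusted p of 0.255, that of Slpi and an olfactory pseudogene. No other tool was run for this test, and the dark zone gate held 64 and 45 IgG cells and 64 and 68 IgM cells, and the size of difference that the test can detect was not simulated.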
